A study of Mus musculus with 6 samples.

How the data were processed

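The series holds 6 Affymetrix Mouse 430 2.0 arrays, each of jejunal RNA from 1 male mouse: wild type mice 1, 3 and 4 and Ifrd1 and Ifrd2 double knockout mice 1, 2 and 3, all on a high-fat diet. Per the labels' protocols, tissue was taken after 3 weeks of the diet, RNA was isolated with TRIzol and columns, and 500 ng was labelled with biotin. The labels name separate mice, so the spread between arrays holds the variation between animals.

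The deposited values are log2 expression levels, 1 per probe set and array; the authors made them with GCRMA 2.18.0, per the submitters' processing notes, and the settings are not given in the sources used here. That the scale is log2 was read from the values, whose quantiles are nearly equal across arrays. GCRMA subtracts a background predicted from probe sequence and normalises the arrays together, so levels near the bottom of the scale hold little information and a fold change from such a level depends on the background model. The number of arrays limits the precision. No pair of arrays within a group was a copy: at least 62.5% of tested probe sets differed by more than 0.1 within each pair.

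Probe sets were named through the platform annotation and the GRCm38.p6 gene table. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none; only those with 1 symbol are named. After removal of 64 control probe sets, those above a log2 value of 4 on at least 3 of the 6 arrays were kept, which left 18013 (15878 with 1 symbol, 499 with several and 1636 with none). Gene positions were used only to find which genes neighbour each other, since the array files name no genome build.

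The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariates), double knockout minus wild type, two-sided, with Benjamini-Hochberg adjustment over the 18013 probe sets and a threshold of 0.05. Errors after fold changes are limma's standard errors. Where all 3 values of a group lay under 4, a named gene's change is given as at least N-fold, with values under 4 raised to 4, and the adjusted p is that of the fit to the deposited values. In data simulated from these arrays, 200 of 18013 probe sets were changed. The fit recovered 11.9% of 67 planted at a log2 change of 0.5, 83.6% of 67 at 1 and all of 66 at 2. There were 7 false calls among 137, and changes of 0.5 were mostly missed. The real arrays gave 805 calls, and the adjusted threshold depends on that number, so the share missed in them was not measured.

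Lists of genes (45, covering lipid handling, digestion, metabolism, growth and the cell types that a piece of jejunum can hold) were written before the data were examined, as were the filter, the tests, the rule for named genes and most alternatives. Symbols were matched directly or, where no gene bears the symbol, through a synonym of 1 gene only. A correction made after the results were seen removed 3 symbols (Sis, Duox2 and Rpl23) that had been matched to other genes; it took 1 gene out of the cytosolic ribosomal proteins and changed no call in the main analysis. Of 975 symbols in the lists, 873 matched a probe set; the others are not analysed here. For each gene the probe set with the highest mean over all arrays was used, and the 39 lists with at least 5 measured genes were tested with camera (preset correlation 0.01, adjusted over the lists). The remaining 6 lists (markers of tuft, enteric nerve, mast, pancreatic acinar and red blood cells, and of colon and stomach) were too small to test after the filter and were tested only in the alternative without it, where tuft cell markers passed (adjusted p = 0.00606, and adjusted p = 0.65 with an estimated correlation) and the others had adjusted p-values between 0.106 and 0.662. Each list's members were also adjusted over the list alone. In data simulated with each gene drawn independently, a shift of 0.5 planted in the 24 ribosome biogenesis genes was called and none of the other lists was. That simulation holds no correlation between genes. It therefore cannot show how often the preset test calls lists whose genes vary together, as those of this list did (estimated correlation 0.53).

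Genes were named by rule: the targeted genes; the 10 with the largest rise and the 10 with the largest fall among those that passed and whose groups did not overlap; up to 4 passing members of each list by p, or up to 2 with the smallest p where none passed; and up to 6 passing genes within 10 Mb of a targeted gene. Not every gene the rule allows is printed. Changed genes near the targeted genes were counted with Fisher's exact test, and RNA quality was compared with an exact permutation test over the 20 splits. Alternatives covered the filter, the normalization, a floor of 4, the variance prior, array weights, the mouse number as a block, leaving out each mouse, the list test and the window. Figures were drawn with matplotlib 3.10.9.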

Results

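Gene expression was measured in the jejunum, the middle part of the small intestine, of 6 male C57BL/6 mice fed a diet rich in milk fat (42% of energy) and cholesterol. The group of 3 double knockout mice lacked both Ifrd1 (TIS7) and Ifrd2 (SKMc15), a pair of related genes described as transcriptional regulators, and the other 3 mice were wild type. The title of the series asks about intestinal lipid absorption and obesity, so the comparison addressed is which jejunal transcripts differ when both genes are lost on a high-fat diet. Each mouse was measured on 1 Affymetrix Mouse 430 2.0 array, and 18013 of 45101 probe sets were bright enough to be tested. Array medians lay between 2.87 and 2.90 on the log2 scale, and the number of arrays per group (n = 3) limits the precision of every value below. The first principal component held 50.0% of the variance and placed the wild type arrays between -32.4 and -17.6 and the double knockout arrays between 19.8 and 35.1.

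Both targeted transcripts were far lower on every double knockout array. Ifrd2 had a mean log2 value of 8.38 ± 0.21 (SD, n = 3) in wild type and 2.66 ± 0.08 in double knockout jejunum. Because all 3 double knockout values lay under the minimum of 4 used here, this is a fall of at least 20.8-fold (limma adjusted p = 2.37e-05). Ifrd1 had 9.92 ± 0.08 in wild type and 5.30 ± 0.83 in double knockout, a log2 fold change of -4.61 ± 0.38 (SE) with a limma adjusted p of 0.00894. Double knockout mouse 1 kept the highest Ifrd1 value, 6.27, against 4.80 and 4.85 in the other two. The labels do not say which exons were removed, so a probe set outside the removed part would check nothing; each gene was measured by 1 probe set. With the 3′ to 5′ difference of control transcripts as a covariate, an alternative added after seeing the data, the Ifrd1 call was lost (-4.93 ± 0.52, limma adjusted p = 0.0777).

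**Figure D1:**
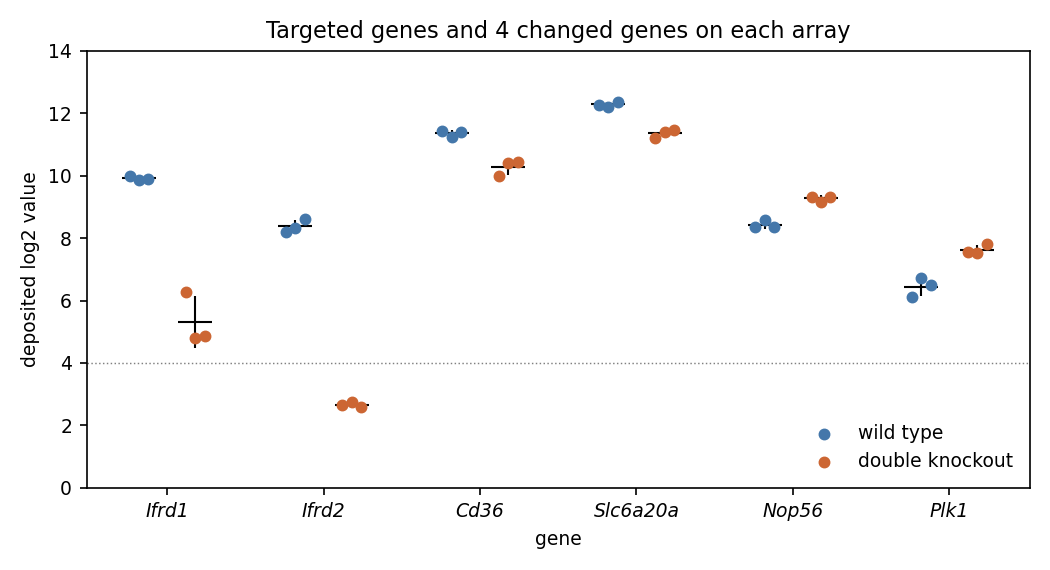
Deposited log2 values on each array for the targeted genes Ifrd1 and Ifrd2 and for Cd36, Slc6a20a, Nop56 and Plk1; blue points are wild type mice, orange points double knockout mice, black lines the mean and its SD (n = 3), and the dotted line the minimum of 4. All Ifrd2 values in double knockout lie under the minimum, around a mean of 2.66, while the wild type mean is 8.38.

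Counting the 2 targeted genes among the lower, 458 probe sets (387 genes) were higher and 347 (248 genes) lower in double knockout jejunum at a limma adjusted p of at most 0.05. Of these, 66 were higher and 100 lower by at least 2-fold. Among the genes with the largest rise were Bcat2 and Bckdhb, which encode a transaminase and a dehydrogenase subunit of branched-chain amino acid breakdown: Bcat2 rose at least 3.13-fold from values under the minimum, and Bckdhb by 1.85 ± 0.20 on the log2 scale. Among those with the largest fall were Hsd3b3, an enzyme of steroid metabolism (-4.69 ± 0.94), and Slc6a20b, a member of the amino acid transporter family, which was at least 2.16-fold lower. Limma adjusted p-values of these 4 genes were 0.0151, 0.0151, 0.0462 and 0.000629. No list of branched-chain amino acid breakdown was tested, so the rise of Bcat2 and Bckdhb does not speak for the pathway. Bcat2 lay in a run of neighbouring changed genes, and Bckdhb and Slc6a20b on the chromosome that carries Ifrd2, where changed genes were in excess.

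The other genes of largest rise were Hddc3, a pyrophosphohydrolase (at least 6.92-fold, adjusted p = 0.0151 by limma), Tmem87a (log2 fold change 3.34 ± 0.47), Abhd1 (3.26 ± 0.21), an immunoglobulin kappa probe set annotated Igk (2.05 ± 0.26), 3110040N11Rik (1.83 ± 0.18) and AI467606 (1.77 ± 0.21). Their limma adjusted p-values ran from 0.00486 for Abhd1 to 0.0255 for Tmem87a. Genes of largest fall included Pramel29 (-2.37 ± 0.21), Gas2, a cytoskeletal protein (-2.32 ± 0.21), and Mcoln3, an endolysosomal cation channel, which was at least 4.94-fold lower. The Mcoln3 call had a limma adjusted p of 0.0327, and those of Gas2 and Pramel29 were 0.00897 and 0.00894. Hsd3b3 varied most between the double knockout mice (SD 2.06 against 0.34 in wild type), and whether its probes also detect close relatives of the gene was not tested.

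For several of the largest changes, probe sets of the same gene disagreed. Paip1, a partner of the poly(A)-binding protein, had log2 fold changes of -4.77 ± 0.63 and -4.62 ± 0.53 on 2 probe sets and -0.31 ± 0.14 on the remaining one, which did not pass. Pclaf, a PCNA-binding protein of dividing cells, was at least 6.13-fold lower on 1 probe set and rose by 0.78 ± 0.10 on the other. Bloc1s6, a subunit of an endosomal sorting complex, rose by 3.00 ± 0.32 on its named probe set and fell by 1.06 on another. Nosip rose by 1.84 ± 0.17 on 1 probe set and fell by 0.46 on the other. Adi1, an enzyme of methionine salvage, fell by 2.17 and by 0.76 on 2 probe sets and rose by 0.49 on the remaining one. Daam1, a formin, was at least 3.58-fold lower on 1 probe set while the other stayed at 0.12 ± 0.10, and the long non-coding RNA Snhg14 fell by 2.86 on 1 probe set while the other stayed at -0.02 ± 0.13. The other Igk probe set stood at 0.43 ± 0.18 and did not pass (limma adjusted p = 0.187). In all, 5 genes (Adi1, Bloc1s6, Nosip, Pclaf and Prxl2c, the last outside the rule for named genes and named after its values were seen) had probe sets that passed in opposite directions.

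Calls on single genes depended on every array. Leaving out wild type mouse 1, 3 or 4 left 27, 26 or 11 probe sets higher and 44, 43 or 21 lower, and leaving out double knockout mouse 1, 2 or 3 left 103, 196 or 22 higher and 101, 239 or 58 lower by the same limma test. All 805 called probe sets kept their direction in these fits. They had been called on the same arrays, so this was largely fixed by the selection and is no measure of stability.

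Genes of ribosome biogenesis, the assembly of ribosomes in the nucleolus, had the smallest camera p of all lists (upward, adjusted p of 3.88e-12 with the preset correlation, and adjusted p = 0.81 with an estimated correlation, which was 0.53 between its members). Of 24 measured members, 16 rose, 0 fell and 8 did not pass over all genes, and 24 rose when adjusted over the list alone. All 24 had positive fold changes, with a median log2 fold change of 0.60, and the list mean was higher in 3 of 3 double knockout mice than in any wild type mouse. Nop56 (0.84 ± 0.11) and Nhp2 (0.70 ± 0.09), components of small nucleolar ribonucleoproteins, rose together with Heatr1 (1.12 ± 0.15) and Nop16 (0.83 ± 0.12), with limma adjusted p-values of 0.0189, 0.0209, 0.0231 and 0.0267. The number of members that rose over all genes was 0, 2 or 0 without wild type mouse 1, 3 or 4 and 1, 9 or 0 without double knockout mouse 1, 2 or 3, while the list median stayed between 0.55 and 0.71. With the 3′ to 5′ covariate the median was 0.46 and 0 members passed.

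Some proliferation genes also rose. Of 35 measured members, 11 rose, 0 fell and 24 did not pass, with 30 higher and 1 lower adjusted over the list alone and a median log2 fold change of 0.48. The mitotic kinase Plk1 rose by 1.18 ± 0.17, the ubiquitin-conjugating enzyme Ube2c by 0.77 ± 0.11, the mitotic spindle protein Hmmr by 0.68 ± 0.08 and the replication helicase subunit Mcm5 by 0.52 ± 0.08 (limma adjusted p 0.0256, 0.0263, 0.0189 and 0.0277). Camera gave an adjusted p of 6.95e-11, and an adjusted p = 0.60 with an estimated correlation. Of the 6 fits that left out 1 mouse, the fit without double knockout mouse 2 left 7 members higher and each of the others 0. With the 3′ to 5′ covariate the median was 0.42 and 0 members passed. Cytosolic ribosomal proteins had positive fold changes for 34 of 36 measured genes, but 0 rose over all genes and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.000113, adjusted p = 0.87 with an estimated correlation). The members with the smallest p were Rps25 at 0.58 ± 0.16 and Rpl14 at 0.52 ± 0.15 (limma adjusted p 0.0870 and 0.0911).

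**Figure D2:**
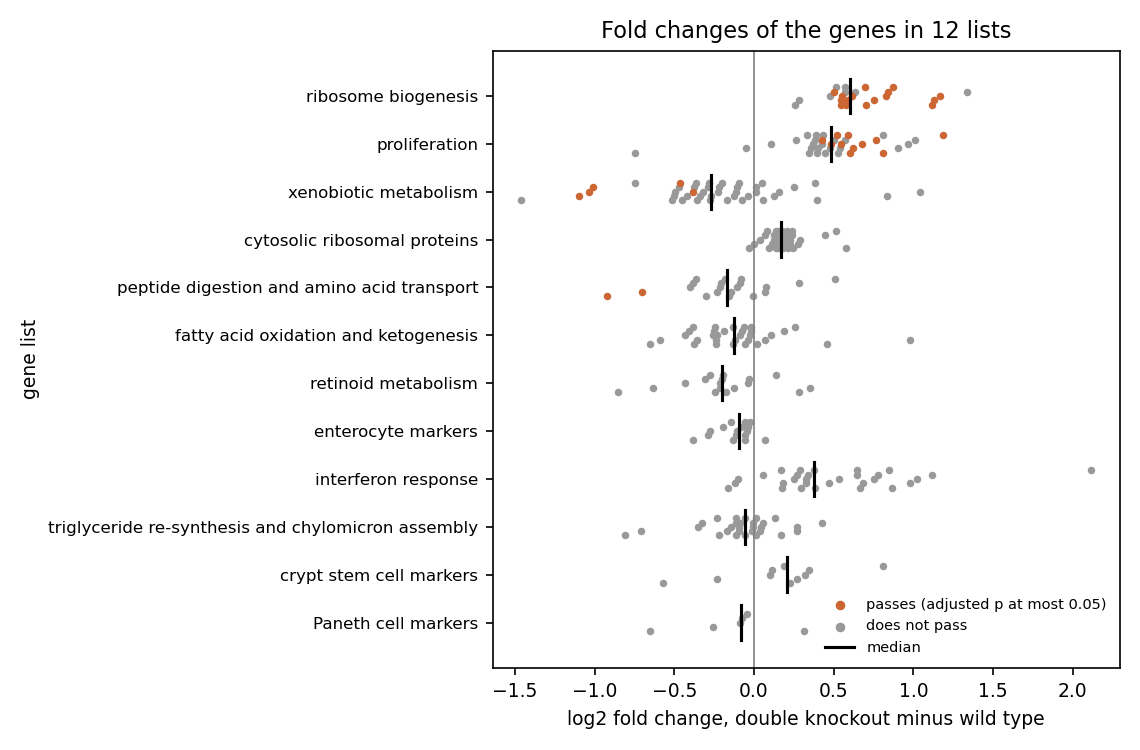
Log2 fold change (double knockout minus wild type) of each measured gene in the 10 lists that passed camera with a preset correlation and in the crypt stem cell and Paneth cell marker lists; each point is 1 gene, orange where its limma adjusted p is at most 0.05 and grey otherwise, and the black bar is the list median. All 24 ribosome biogenesis genes lie above 0, with a median of 0.60, and the median of the xenobiotic metabolism genes is -0.27.

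Some genes of xenobiotic metabolism fell. Of 43 measured members, 0 rose, 5 fell and 38 did not pass, with 1 higher and 17 lower adjusted over the list alone (median -0.27). The list mean differed by -0.23 on the log2 scale, with a 95% interval over arrays of -0.48 to 0.02 that includes 0. The glutathione transferase Gsta3 fell by 1.09, the glucuronosyltransferase Ugt2b36 by 1.03, and the cytochromes P450 Cyp2j6 and Cyp3a25 by 1.01 and 0.46 on the log2 scale (limma adjusted p 0.0385, 0.0169, 0.0231 and 0.0344). Camera gave an adjusted p of 6.18e-07, and an adjusted p = 0.81 with an estimated correlation. No member of the list passed without wild type mouse 1, 3 or 4 or double knockout mouse 3, 2 fell without double knockout mouse 1 and 5 without double knockout mouse 2. With the 3′ to 5′ covariate the median was -0.23, the list mean differed by -0.14 (95% interval -0.50 to 0.22) and 0 members passed.

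Among the genes of lipid absorption that the title points to, few passed. Cd36, a fatty acid transporter of the enterocyte brush border, fell by 1.09 on its brightest probe set (SE 0.14, limma adjusted p = 0.0210) and by 0.99 and 1.44 on its other two, in 3 of 3 double knockout mice. It was the only one of 13 measured genes of fatty acid uptake and trafficking to change, against 3 lower and 0 higher adjusted over the list alone (camera adjusted p = 0.265). Fry, which asks whether the members of a list move one way without comparing them with other genes, gave this list an adjusted p of 0.0155 downward, and its mean was lower in 3 of 3 double knockout mice than in any wild type mouse, with a median log2 fold change of -0.03 over its genes. Triglyceride re-synthesis and chylomicron assembly held 29 measured genes, of which 0 rose and 0 fell either over all genes or adjusted over the list alone (median -0.06, camera adjusted p = 0.0453, adjusted p = 0.89 with an estimated correlation). Its members with the smallest p were Apob, the structural protein of chylomicrons, at -0.33 ± 0.08, and Plpp1 at -0.35 ± 0.09 (limma adjusted p 0.0699 and 0.0739). For fatty acid oxidation and ketogenesis, 0 of 32 measured genes passed over all genes or adjusted over the list alone (median -0.12, camera adjusted p = 0.00544, adjusted p = 0.89 with an estimated correlation), with Decr2 at -0.41 ± 0.09 and Ehhadh at -0.38 ± 0.10 (limma adjusted p 0.0586 and 0.0786).

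Among lipid-related lists that did not pass camera, the desaturase Fads1 rose by 0.80 ± 0.12 in fatty acid synthesis (camera adjusted p = 0.265) and Fdps, an enzyme of the isoprenoid pathway, by 0.54 ± 0.10 in cholesterol biosynthesis (camera adjusted p = 0.157). Adjusted over the list alone, 2 of 19 and 4 of 21 measured genes of these lists were higher and 0 lower. The transcription factor Hnf4g fell by 0.78 and the lipase Aadac by 0.47, each the only member of its list to pass over all genes; adjusted over the list alone, 1 gene was higher and 1 lower among 19 lipid transcription factors, and 0 higher and 1 lower among 17 lipases. Limma adjusted p-values of Fads1, Fdps, Hnf4g and Aadac were 0.0267, 0.0416, 0.0412 and 0.0423. The sterol transport and LXR target list (18 measured genes) and the bile acid and FXR target list (7) had 0 passing members over all genes or adjusted over the list alone, and Abcg8, a sterol efflux transporter subunit, stood at -0.77 ± 0.20 (limma adjusted p = 0.0775). Of these lists, cholesterol biosynthesis passed camera upward in 2 of 14 alternatives with the preset correlation, and sterol transport in 3 and lipases in 1 downward.

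Single genes of other absorptive functions also passed. In peptide digestion and amino acid transport, the imino acid transporter Slc6a20a fell by 0.92 (SE 0.10) and the brush border protease Mep1a by 0.70 (SE 0.14), 2 of 20 measured genes over all genes, with 1 higher and 2 lower adjusted over the list alone. Camera gave this list an adjusted p of 0.00544 and an adjusted p = 0.89 with an estimated correlation (limma adjusted p 0.0151 for Slc6a20a and 0.0438 for Mep1a). Retinoid metabolism had 0 of 17 genes past the threshold over all genes or adjusted over the list alone (median -0.20, camera adjusted p = 0.00684, adjusted p = 0.87 with an estimated correlation), with Adh4 at -0.85 ± 0.20 (limma adjusted p = 0.0616). The trehalose-splitting enzyme Treh fell by 0.74 and the hexokinase Hk2 rose by 1.15 ± 0.17 among 17 genes of carbohydrate digestion and sugar transport, a list with 3 higher and 3 lower genes adjusted over the list alone and a camera adjusted p of 0.913. Cubn, an endocytic receptor, fell by 0.78, the only one of 10 ileum markers to change over all genes or adjusted over the list alone (camera adjusted p = 0.160). Limma adjusted p-values of Treh, Hk2 and Cubn were 0.0303, 0.0257 and 0.0186. Slc6a20a and Treh lie on the chromosome that carries Ifrd2, where changed genes were in excess.

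Markers of the cell types of the jejunum were measured in the same way. Enterocyte markers had negative fold changes for 15 of 16 genes, with a median of -0.09, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.00684, adjusted p = 0.81 with an estimated correlation); lactase, Lct, stood at -0.29 ± 0.08 (limma adjusted p = 0.0847). Crypt stem cell markers (10 genes, median 0.21, camera adjusted p = 0.473), Paneth cell markers (6 genes, median -0.08, camera adjusted p = 0.358) and goblet cell markers (13 genes, median -0.02, camera adjusted p = 0.588) did not pass. Adjusted over the list alone, 1 crypt stem cell marker was higher and 0 members of the other two lists passed. Paneth cell markers passed downward in 2 alternatives (camera adjusted p = 6.56e-05 with the mouse number as a block and 0.0424 without wild type mouse 4) and goblet cell markers in 1 (0.000754 with the block). Wild type mouse 4 and double knockout mouse 2 share their number with no other mouse, so the fit with the block rests on mice 1 and 3 of each group. Of the non-epithelial lists, fibroblast and matrix markers had 13 of 13 positive fold changes (median 0.47) and a camera adjusted p of 0.0519, and macrophage and dendritic cell markers had 9 of 10 (median 0.36) and 0.265. Neither list passed here, and both depended on the settings. With an estimated correlation each had a camera adjusted p of 0.89. Of 14 alternatives with the preset correlation, the fibroblast list passed upward in 8 (adjusted p = 0.00251 without the filter on dim probe sets, 0.0475 with a stricter filter, 0.0452 after quantile normalization, 0.0368 after median centring), but not without wild type mouse 4 or double knockout mouse 2 or 3. The macrophage list passed in 3 (0.0249 without the filter, 0.0416 without double knockout mouse 1, 0.000410 with the 3′ to 5′ covariate). Without double knockout mouse 2, camera's direction for the macrophage list turned downward, which is relative to the other genes. The list mean lay at -0.09 and 0.30 from the wild type mean in double knockout mice 1 and 3. Rgs13, a tuft cell marker, fell by 1.00 (SE 0.17, limma adjusted p = 0.0321), but only 4 genes of its list were bright enough, too few for the test; without the filter, camera gave its 11 genes, of which 1 fell and 0 rose, an adjusted p of 0.00606 downward and an adjusted p = 0.65 with an estimated correlation. The antimicrobial lectin Reg3a fell by 0.68 (limma adjusted p = 0.0282), the Wnt feedback gene Nkd1 rose by 0.58 ± 0.11 (0.0412) and the endoplasmic reticulum gene Creld2 by 0.60 ± 0.10 (0.0313), each in a list that did not pass camera. Adjusted over the list alone, 0 genes were higher and 1 lower in the list of Reg3a, 4 and 1 in that of Nkd1, and 1 and 0 in that of Creld2. In the 12 other lists tested, among them MHC class II, heat shock, oxidative phosphorylation, lymphocyte, endothelial and smooth muscle genes, 0 members passed over all genes and camera adjusted p-values lay between 0.227 and 0.933. Adjusted over the list alone, 4 heat shock and 2 MHC class II genes were higher, 1 circadian clock gene was lower, and 0 members of the others passed. The MHC class II list passed upward without wild type mouse 1 (camera adjusted p = 0.00578) and with the 3′ to 5′ covariate (0.0390), smooth muscle markers downward with the covariate (0.00855) and enteroendocrine markers downward with the mouse number as a block (0.0380).

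**Figure D3:**
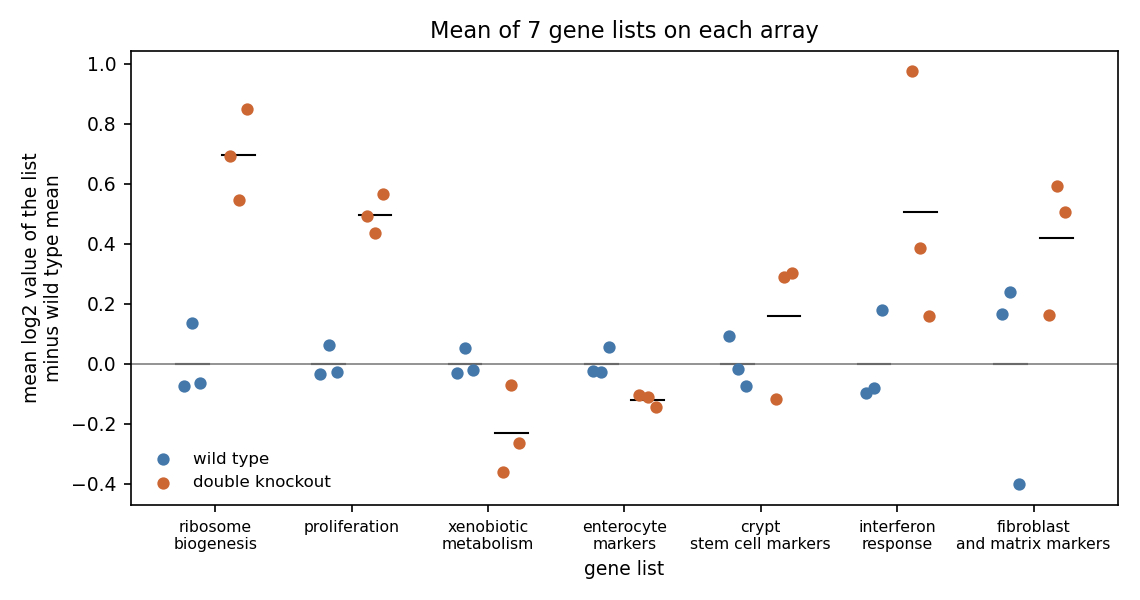
Mean log2 value of 7 gene lists on each array, minus the wild type mean; blue points are wild type mice, orange points double knockout mice and black lines group means (n = 3). Ribosome biogenesis lies at 0.69, 0.54 and 0.85 in the double knockout mice and between -0.07 and 0.14 in wild type, while the fibroblast and interferon lists overlap between the groups.

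Of the 39 lists tested, 10 passed camera with a preset correlation, 4 upward and 6 downward, and 0 passed with an estimated correlation, where adjusted p-values started at 0.604. That form of camera also uses only the residual degrees of freedom of the 6 arrays, so it has little power whatever the correlation. Fatty acid uptake and trafficking, with an estimated correlation of -0.08, went from a camera adjusted p of 0.265 to 0.867. Not passing with an estimated correlation therefore does not show that a list is unchanged. In the other 9 ways of splitting the 6 arrays into 3 and 3, between 8 and 17 lists passed the same preset test. Ribosome biogenesis, proliferation, xenobiotic metabolism and cytosolic ribosomal proteins passed in all 14 alternatives with the preset correlation. Triglyceride re-synthesis did not pass in 8 of the 14, among them the fits without wild type mouse 3 (camera adjusted p = 0.0878) or 4 (0.0903) or double knockout mouse 3 (0.187). Fatty acid oxidation did not pass without wild type mouse 3 (0.0615) or double knockout mouse 1 (0.121), nor did interferon response (0.0878 and 0.242). Retinoid metabolism did not pass without double knockout mouse 1 (0.106), and peptide digestion without double knockout mouse 2 (0.0518).

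Changed genes were concentrated around Ifrd2. Within 10 Mb of the targeted genes (gene order from the GRCm38.p6 assembly), 16 of 151 measured genes changed, or 10.6%, against 445 of 9498 elsewhere, or 4.69% (odds ratio 2.41, 95% interval 1.33 to 4.10, Fisher's exact p = 0.00285, two-sided). Around Ifrd2 there were 14 of 120, 7 higher and 7 lower (Fisher's exact p = 0.00170), and around Ifrd1 2 of 31 (Fisher's exact p = 0.659). Pik3r4, a subunit of a lipid kinase complex of autophagy, fell by 1.26 (SE 0.11), the kinase Mapkapk3 by 1.10 (SE 0.10) and the lysosomal galactosidase Glb1 by 1.20 (SE 0.13). Glyctk, glycerate kinase, was at least 1.67-fold lower, while Pcbp4, an RNA-binding protein, and Acy1, an aminoacylase, rose by 1.12 ± 0.12 and 0.86 ± 0.10. Limma adjusted p-values of these 6 genes lay between 0.00897 and 0.0151. On the rest of the chromosome that carries Ifrd2, which holds Bckdhb, Pclaf, Slc6a20a, Slc6a20b and Treh, 33 of 427 genes changed (7.73%, Fisher's exact p = 0.00455). Fits without 1 mouse gave odds ratios of 8.58, 7.11 and 8.48 without wild type mouse 1, 3 and 4 and 5.05, 4.33 and 7.35 without double knockout mouse 1, 2 and 3, with 4, 3, 2, 8, 15 and 4 changed genes near the targeted genes against 16 in the full fit, so the larger ratios rest on fewer genes. Of the genes with the largest rise, Tmem87a and Bloc1s6 lay in a run of neighbouring changed genes on another chromosome, and Bcat2 and Nosip in a further one.

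**Figure D4:**
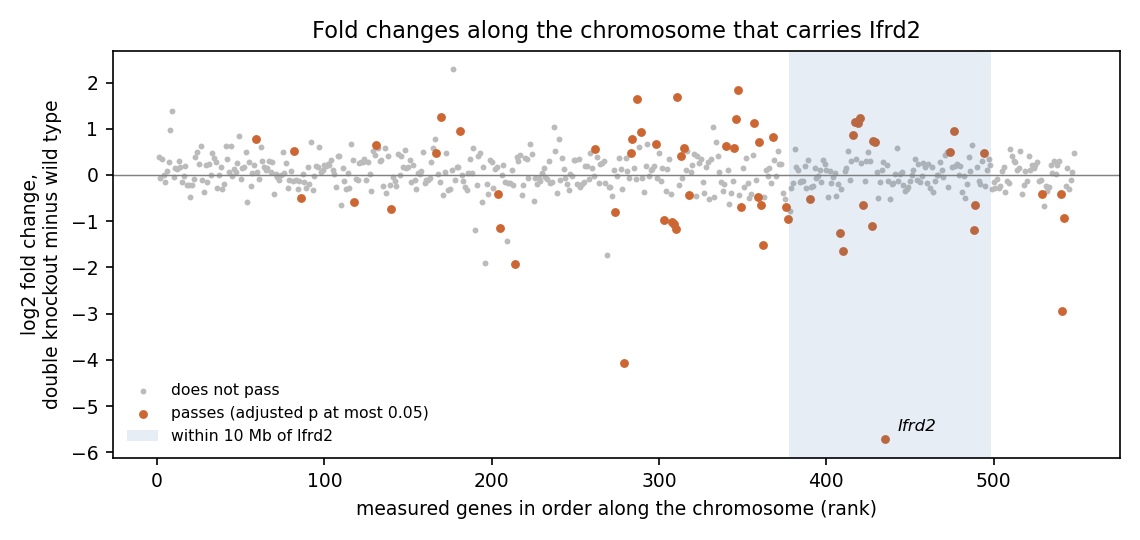
Log2 fold change (double knockout minus wild type) of each measured gene on the chromosome that carries Ifrd2, in gene order, taking for each gene the probe set with the smallest p; orange points have a limma adjusted p of at most 0.05 and the shaded band holds the genes within 10 Mb of Ifrd2. Both higher and lower genes occur in the band, such as Pcbp4 at 1.12 and Pik3r4 at -1.26.

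RNA quality was compared through the 3′ to 5′ difference of the beta-actin and Gapdh control probe sets, which grows as RNA is degraded. It was 0.40 ± 0.08 (SD, n = 3) log2 units in wild type and 0.54 ± 0.11 in double knockout, a difference of 0.14 (exact permutation p = 0.2, two-sided, where 3 against 3 cannot go below 0.1). The values were 0.35, 0.49 and 0.36 in wild type mice 1, 3 and 4 and 0.60, 0.41 and 0.61 in double knockout mice 1, 2 and 3. With this difference as a covariate, limma called 5 probe sets higher and 12 lower.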

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

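The fits with the 3′ to 5′ covariate, those without the chromosome of Ifrd2, the count over any kept probe set and the estimated correlation without the filter were chosen after seeing the data; all others were fixed before the data were examined. The 458 higher and 347 lower probe sets became 265 and 207 without the filter on dim probe sets, 918 and 727 with an intensity trend, 1438 and 1041 at an adjusted p of 0.1, 66 and 100 with at least a 2-fold change, and 5 and 12 with the 3′ to 5′ covariate; the stricter filter gave 710 higher. A looser threshold and an added condition account for the change at 0.1 and with the 2-fold limit. Without the filter, more probe sets were tested (45037) and the variance prior was estimated anew, and these were not separated. For the other alternatives the cause was not tested. Mouse numbers 1 and 3 occur in both groups, with correlations of their deviations of 0.02 and 0.30. Mice with unlike numbers were not compared in this way, so whether the numbers pair the mice stays open. With the number as a replicate block, 2 probe sets were higher and 11 lower, and Ifrd1 stood at -4.36 (limma adjusted p = 0.103). That fit has fewer degrees of freedom and rests on mice 1 and 3 of each group, since numbers 2 and 4 occur once. Over the fits without 1 mouse, the counts ranged from 11 to 196 higher and 21 to 239 lower. Ifrd1 stood at -4.93 with the covariate (limma adjusted p = 0.0777, against 0.000146 to 0.103 over its other alternatives), and the cause was not tested. In place of 10 lists, 0 passed with an estimated correlation, with or without the filter, and 5 passed fry, which does not compare a list with other genes (4 of the 10, and fatty acid uptake and trafficking); leaving out 1 mouse gave 9 to 12, not always the same ones. Over the 14 alternatives with the preset correlation, 4 of the 10 always passed (ribosome biogenesis, proliferation, xenobiotic metabolism, cytosolic ribosomal proteins); triglyceride re-synthesis was lost in 8, interferon response in 3, fatty acid oxidation, retinoid metabolism and peptide digestion in 2 each and enterocyte markers in 1, and 11 other lists passed in at least 1. Ifrd2, the excess of changed genes near the targeted genes (odds ratios 1.75 to 8.58, on 2 to 29 genes) and the RNA quality difference kept their direction and their side of the threshold under every alternative run for them. All 52 named probe sets that passed kept their direction in every fit, which their selection on these arrays largely fixes. Of them, 8 passed in each fit without 1 mouse. Dim signal limits genes such as Hddc3 and Bcat2, whose wild type values lay under 4.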

Other observations

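The tests on the 3 added gene lists, on list means with a covariate or against crypt markers, on the share of lower genes, on windows and on the position of single mice were chosen after the results were seen; the test on list members not seen first was set before its result. Some enzymes that supply nucleotides, polyamines and one-carbon units were higher in double knockout jejunum. A list of 27 such genes was written after Srm, Cad, Mthfd2 and Phgdh had been seen among the higher genes; 7 rose, 0 fell and 25 had positive fold changes (median 0.50). Over the 23 members not seen first, the median was 0.45, 21 were positive and 4 rose. Their list mean lay above every wild type array on 3 of 3 double knockout arrays. Unadjusted p-values were 0.000120 by fry, 4.54e-06 by camera and 0.00905 by camera with an estimated correlation. They cannot be set beside the values of the lists written before the data were examined, which are adjusted over all lists tested. No fit without 1 mouse, with the mouse number as a block or with the covariate is given for the 3 added lists. The 4 members that rose were Ctps (0.80 ± 0.09), Gmps (0.66 ± 0.08), Gart (0.80 ± 0.16) and Atic (0.61 ± 0.12), enzymes of pyrimidine and purine synthesis. Their limma adjusted p-values were 0.0151, 0.0201, 0.0436 and 0.0479. Srm, spermidine synthase, rose by 1.64 ± 0.20 and Cad, which starts pyrimidine synthesis, by 1.02 ± 0.13 (limma adjusted p 0.0173 and 0.0189).

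Cytosolic aminoacyl-tRNA synthetases and mitochondrial ribosomal proteins had smaller positive shifts. Of 19 synthetases 18 had positive fold changes (median 0.22) and 2 rose, Vars (0.89 ± 0.13, limma adjusted p = 0.0251) and Farsa (1.10 ± 0.18, 0.0308); camera gave p = 0.000211, and p = 0.0897 with an estimated correlation. Of 53 mitochondrial ribosomal proteins 48 had positive fold changes (median 0.20) and 5 rose (camera p = 2.71e-06, and p = 0.110 with an estimated correlation). The camera p-values of both lists are likewise unadjusted. Interferon response genes had positive fold changes for 27 of 30 (median 0.38, camera adjusted p = 0.0345, adjusted p = 0.89 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone; the list mean was 0.97, 0.38 and 0.16 above the wild type mean in double knockout mice 1, 2 and 3.

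With 10 splits of 6 arrays, no share of splits can fall under 0.05. The real split gave 458 probe sets higher and 347 lower, and the highest count on either side in another split was 10; in each case 1 of the 10 splits, the real one, reached the real count. It gave 10 lists, while another split gave 17 and 7 of the 10 splits gave at least 10. The preset test thus often calls as many lists in splits that mix the genotypes, and the cause was not tested.

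The rise of ribosome biogenesis and proliferation genes was weighed against RNA quality and tissue composition. With the 3′ to 5′ difference as a covariate, the rise of the list mean went from 0.70 ± 0.11 (SE) to 0.52 ± 0.07 for ribosome biogenesis (95% interval 0.29 to 0.74) and from 0.50 ± 0.05 to 0.42 ± 0.03 for proliferation (0.31 to 0.53). A linear effect of this difference thus did not account for the whole of the list shifts. The difference rests on beta-actin and Gapdh alone and varied partly with genotype, so RNA quality as the whole cause cannot be excluded. The calls on single genes ended in the fit with the covariate, where the fold changes were smaller and 1 more term was estimated. A larger share of crypt in the double knockout pieces would raise crypt stem cell markers at least as much. The rise of ribosome biogenesis exceeded theirs by 0.54 ± 0.18 (95% interval 0.03 to 1.05), but with the covariate by 0.25 ± 0.14 (-0.19 to 0.70), and that of proliferation by 0.34 ± 0.15 (-0.08 to 0.76) and 0.16 ± 0.17 (-0.39 to 0.71). Of 10 crypt markers, 8 had positive and 2 negative fold changes, among them Ascl2 at 0.81 and Rnf43 at -0.57 (limma adjusted p 0.0646 and 0.0925). The interval of the excess stayed above 0 only for ribosome biogenesis without the covariate. Crypt share and a change within crypt cells thus cannot be told apart for either list. Whether dividing cells were more numerous was not tested; counts of labelled dividing cells per crypt would decide it.

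Changed genes around Ifrd2 may reflect strain variants under the probes, chromosome carried along from the strain in which the gene was targeted, or the loss of Ifrd2 itself. Variants under probes lower the signal, and 50.0% of the 14 changed genes within 10 Mb of Ifrd2 were lower (exact 95% interval 23.0% to 77.0%). Over all genes, counted by 1 probe set each, 308 were higher and 155 lower, so the share of lower genes was not smaller near Ifrd2. The 14 also hold genes that would change without any variant, as 4.69% of genes did elsewhere. This share therefore cannot decide whether variants are the whole cause. Among genes changed at least 2-fold with several probe sets, the probe sets disagreed for 5 of 11 on this chromosome and 15 of 44 elsewhere (Fisher's exact p = 0.503). The excess reached beyond 10 Mb (odds ratio 1.76 on the rest of the chromosome, 95% interval 1.18 to 2.55), as a carried-along segment could give, but without genotypes a segment and an effect of losing Ifrd2 cannot be told apart.

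Runs of neighbouring changed genes also occurred on chromosomes that carry neither targeted gene. Over 801 windows of 5 Mb, 4 such windows passed a familywise permutation test, the lowest at p = 0.000999, the smallest that 1000 permutations can give, which argues against chance placement; they form 2 runs, each with 7 genes called at least 2-fold changed, among them Bcat2, Nosip, Abcc6 and Hps5 in the first and Tmem87a, Bloc1s6, Ganc and Mga in the second. With genes changed at least 2-fold at an unadjusted p of at most 0.01 added, each run held 11 genes, and 1 double knockout mouse lay closest to wild type for most of them: mouse 3 for 8 of 11 in the first run, as for Hps5 (5.36, 5.48 and 6.47 in double knockout mice 1, 2 and 3, 7.22 to 7.38 in wild type) but not for Grwd1, Ruvbl2 or Siglecf, and mouse 2 for 10 of 11 in the second, as for Tmem87a (7.82, 6.33 and 8.34, against 4.09 to 4.28) but not for Mapkbp1. On a scale from wild type (0) to the mean of the other 2 mice (1), that mouse's median position differed from the one for changed genes elsewhere. The difference was -0.36 in the first run (permutation p = 0.00948 after multiplying by 3 for the choice of mouse, and 0.00993 over called genes alone). In the second run it was -0.31 (0.0258, but 0.147 over called genes alone). The permutation treats neighbouring genes on 1 array as independent, which they may not be, so these p-values can be too small. A weaker change over that mouse's whole array therefore stays open in both runs. Over the lower genes that mouse lay at a median of -1.20 and -1.02 log2 units from wild type, against -2.08 and -1.90 for the other 2 mice. Over called genes alone the values were -1.38 and -1.06, against -1.92 and -1.59. A candidate explanation is segments of another strain, in 2 copies in some mice and 1 in others. With 1 wild type copy left and a signal proportional to the copies, lower genes would lie at most 1 log2 unit below wild type. These medians lie beyond that limit, but a fold change to a level near the bottom of the scale depends on the background model, so the limit is not strict. The quartiles over the lower genes (-1.37 to -0.79 and -1.12 to -0.89) include the limit. The explanation therefore stays open, and genotypes would decide it.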
